A study of Homo sapiens with 12 samples.

How the data were processed

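The series held 12 arrays of RNA from PC3 xenograft tumours, 3 for each of 4 groups (vector or PML, vehicle or palbociclib), and the groups were taken from the sample titles. Per the labels' protocols, RNA was extracted from snap-frozen tumours with RNeasy columns, labelled as biotinylated cRNA with the Ambion WT kit and hybridised to Affymetrix whole-transcript human arrays. Per the submitters' processing notes, the deposited values are log2 intensities made by RMA in Affymetrix Expression Console (versions not given in the sources used here). RMA includes background correction and quantile normalization, and the deposited log2 intensities were used without a further transformation. No genome came with the series, so nothing was placed on coordinates.

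Of 53617 transcript clusters, 16098 carried 1 gene symbol and 37519 carried none in the table used here. The symbols covered 14884 genes, and 779 of them had more than 1 cluster, of which the one with the highest mean was kept. For some named genes the other cluster differed widely. Examples in the interaction are GAS6-AS1, DES and CLSPN (0.19, 0.09 and 0.42, against 0.72, 0.65 and -0.24 for the cluster kept). DES with PML under palbociclib had 0.09 against 0.70. SULF2 under palbociclib had -0.29 against -1.08 in vector tumours, -0.25 against -1.37 in PML tumours and -0.27 against -1.22 averaged. CLSPN and CCN2 under palbociclib in PML tumours had 0.15 and -0.08, against -0.86 and 0.51. A gene was tested where its log2 intensity was at least 5 on at least 3 of the 12 arrays, which left 8862 genes and put 6022 below the floor. Signal over background limits the dim genes. Among the genes named in the text, ADGRF4, AGR2, ANKRD1, CCL2, IFIH1, KRTAP3-1, MAP2K6, MBOAT1, MX2, MYLK, OLR1, SCEL, STOX1 and TET2 passed in at least 1 comparison of 2 groups with 1 or both group means below that floor. The size of such a change, and of an averaged effect that contains it, is uncertain. The median log2 intensity of the tested genes lay between 5.96 and 6.30 per array, and the residual SD had a median of 0.172 over the 12 arrays.

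Group means were fitted to all 12 arrays with limma (version 3.58.1, R 4.3.3), with moderated two-sided tests and Benjamini-Hochberg adjustment over the tested genes, and genes with an adjusted p under 0.05 were called. The comparisons were palbociclib against vehicle in vector and in PML tumours, PML against vector under vehicle and under palbociclib, the interaction, PML with palbociclib against vector with vehicle, and the 2 averaged effects. SE is the moderated standard error of a log2 fold change. The palbociclib effects of the 2 infections were also correlated across genes.

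Before the data were examined, 29 lists of 709 genes were written from general knowledge, with 429 genes named on the array and 336 tested. They were E2F targets and DNA replication, G2/M and mitosis, the cyclin D, CDK4/6 and RB family, DNA and histone methylation enzymes, PML nuclear body proteins, interferon-stimulated genes, MHC class I antigen presentation, senescence-associated secretory factors, p53 targets, lysosome and autophagy, cholesterol synthesis, hypoxia response, unfolded protein and amino acid stress, ribosome biogenesis and MYC targets, oxidative phosphorylation, immediate early genes, heat shock proteins, epithelial keratins and junctions, mesenchymal genes, androgen receptor targets and 9 lists of host cell markers. The 22 lists with at least 5 tested genes went to camera in limma with a preset correlation of 0.01, adjusted over the lists, which asks whether a list moved against the other genes. Camera with the correlation estimated from the arrays and fry were the alternatives. Members are also given adjusted over the list alone, a test chosen for reading a list and not for calling genes. The list of methylation enzymes also holds proteins that bind methyl marks, such as CBX3, CBX5 and UHRF1. It holds enzymes that act in their removal as well, such as KDM1A and TET2.

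The genes named were PML, CDK4, CDK6, CCND1, RB1, E2F1, CDKN1A, DNMT1 and MKI67 in each comparison, the 6 with the largest changes up and down among the calls (with none, the 3 smallest p each way), the 3 members with the smallest p in the direction of each called list, and the 2 brightest members of each host list. The fixed genes and the list members may be left out for the combined and averaged effects. CDKN1A had no cluster with its symbol and was not analysed here. Another gene that the rule names is not reported here. Genes named outside this rule are said to be so or stand as the full set of called members, or of members that did not pass, of a list, which was chosen after the values were seen. Host marker probes may also bind mouse RNA, which was not tested.

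Alternatives written before the data were examined were no intensity filter, a floor of 6, quantile normalization again, median centring, the mean of a gene's clusters, every cluster on its own, a fit on the groups of a comparison alone, array weights, eBayes with trend and robust set, the replicate number as a block, a covariate of 12 fibroblast, endothelial and myeloid markers, a fold of at least 2 as well, an adjusted p under 0.1, and leaving out each array in turn. Chosen after seeing the data were the counts and list tests without PML palbociclib replicate 3 beside each result, the estimated correlation without it, and the gene-by-gene method of the array weights, because the default did not converge.

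The code was tested on simulated data of 8862 genes with 100 changed genes per size. At a log2 change of 1 it recovered 97% (palbociclib in vector tumours), 99% (palbociclib in PML tumours), 99% (PML under vehicle), 100% (PML under palbociclib), 78% (interaction), 98% (both together), 100% (palbociclib averaged) and 100% (PML averaged). At 0.5 it recovered 39%, 34%, 37%, 43%, 9%, 39%, 85% and 82% in the same order, and 4.23%, 7.64%, 3.55%, 4.03%, 7.45%, 2.14%, 3.65% and 4.71% of the calls were false. With the lysosome list shifted by 0.5, that list was the 1 of 22 called. Without correlation between the simulated genes, this does not show that the preset correlation suits the real lists. Counts were also compared with other splits of the samples. For the interaction, the way of splitting was changed after the first splits were seen: the average effects were removed first.

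The median or mean log2 fold change of a list had the sign opposite to its test in 30 list results, of which 2 were called, namely the hypoxia response under palbociclib in PML tumours and smooth muscle markers in the interaction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The 37519 clusters without a symbol enter no comparison of the report; 11955 of them passed the floor, were fitted on their own, and are given in the closing section.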

Results

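Gene expression was measured in xenograft tumours of PC3, an established human prostate cancer line that lacks functional p53. The cells had been infected with a retrovirus carrying either no insert (vector) or PML, the scaffold protein of PML nuclear bodies and a tumour suppressor, and selected with puromycin at 5 µg/ml for 3 days. BALB/c nude mice 6 weeks old received 1000000 cells under the skin of both flanks. They were then given by gavage either sodium lactate buffer (vehicle) or palbociclib, an inhibitor of the cyclin D kinases CDK4 and CDK6, at 100 mg/kg per day for 5 days. RNA from snap-frozen tumours was hybridised to whole-transcript human arrays. Infection and agent were crossed, giving 4 groups of 3 arrays each and 12 arrays in all. The labels do not say which tumours shared a mouse, so tumours of a group may not be independent. The p-values measure the spread between these samples, shared over the 4 groups, and may be too small as statements about mice. The design asks what palbociclib changed with and without added PML, what PML changed with and without palbociclib, and whether the effects differed.

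The table held deposited log2 intensities for 53617 transcript clusters on each array, from 0.04 to 13.73. Of 14884 genes with a named cluster, 8862 were bright enough to test, and arrays had between 7908 and 8370 genes above the floor. The median log2 intensity of the tested genes was lowest, at 5.96, on PML palbociclib replicate 3 and reached 6.30 on the other 11 arrays. That array also had a narrower spread of all clusters (SD 1.88 against 2.05 to 2.11). Its Pearson r with the other arrays across clusters was 0.936 to 0.954, where genes are not independent replicates. It took the extreme score of 48.8 on the first principal component, against -15.3 to 9.98 for the others. Every count that opens a comparison is therefore also given without that array, an alternative added after seeing the data. The median residual SD was 0.172 with that array and 0.113 without it. Standard errors shared over the groups may therefore be too small for comparisons with the PML palbociclib group and too large for the others. The number of arrays limits the precision of each value.

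**Figure D1:**
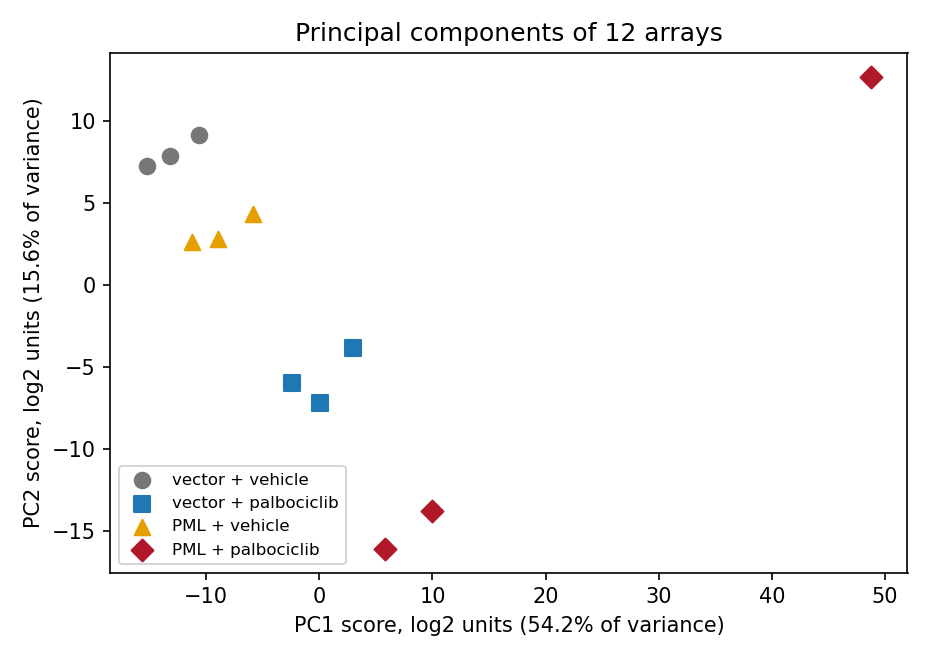
Scores of the 12 arrays on the first principal component (x axis, log2 units, 54.2% of the variance) and the second (y axis, log2 units, 15.6%), over the 8862 tested genes, with 1 symbol per array and 1 colour and shape per group. PML palbociclib replicate 3 lies at 48.8 on the first component, and the other 11 arrays lie between -15.3 and 9.98.

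PML itself was the check of the infections. Its log2 intensity was 6.76, 6.69 and 5.88 in the vector vehicle tumours and 7.35, 6.36 and 6.38 in the vector palbociclib tumours. It was 8.52, 8.18 and 8.72 in the PML vehicle tumours and 8.06, 7.86 and 7.77 in the PML palbociclib tumours, so each PML array lay above each vector array. PML rose 4.09-fold with its vector under vehicle (log2 fold change 2.03, SE 0.26, n = 3 per group, adjusted p = 0.00541) and 2.29-fold under palbociclib (log2 fold change 1.20, SE 0.26, adjusted p = 0.0185). With a covariate for host markers PML did not pass under palbociclib (1.03, adjusted p = 0.0777).

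Under palbociclib in vector tumours 103 of 8862 genes rose and 128 fell (n = 3 per group), against 266 and 226 after quantile normalization again and 292 and 287 after median centring. HEPHL1, a copper-dependent ferroxidase, rose 7.93-fold (log2 fold change 2.99, SE 0.15, adjusted p = 9.84e-08). KRTAP2-3, which encodes a hair keratin-associated protein, rose 5.72-fold (2.52, SE 0.17, adjusted p = 1.62e-06). KRTAP3-1, of the same class, rose too (3.04, SE 0.33, adjusted p = 0.000231), from a vector vehicle mean of 3.98 below the floor of 5, so the size of its change is uncertain. The steepest fall was in HAS2, a hyaluronan synthase (log2 fold change -1.23, SE 0.13, adjusted p = 0.000187). Without PML palbociclib replicate 3, which enters this comparison only through the shared estimate of spread, 427 genes rose and 1051 fell. All 231 genes passed again, and their fold changes are the same by construction.

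The other leading genes under palbociclib in vector tumours were ESM1, a secreted proteoglycan (log2 fold change 1.71, SE 0.15), CPA4, a carboxypeptidase (1.69, SE 0.13), and GKN2, a gastrokine (1.53, SE 0.20), which rose. SULF2, an extracellular heparan sulfatase (-1.08, SE 0.16), MBOAT1, a phospholipid acyltransferase (-1.05, SE 0.19), FZD8, a Wnt receptor (-0.96, SE 0.16), WDR76 (-0.95, SE 0.12) and GPSM2, a protein of spindle orientation (-0.91, SE 0.17), fell. The keratin-associated genes belong to families of near-identical members, so their identity on the array is uncertain. MKI67, a marker of proliferating cells, fell by 0.69 on the log2 scale (SE 0.13, adjusted p = 0.0119). DNMT1, the maintenance DNA methyltransferase, missed the threshold (-0.57, SE 0.15, adjusted p = 0.0526), as did CDK4 (-0.44, SE 0.17, adjusted p = 0.229), CDK6 (0.28, SE 0.11), CCND1, which encodes cyclin D1 (0.19, SE 0.13), RB1 (-0.15, SE 0.14), E2F1 (-0.19, SE 0.19) and PML (0.26, SE 0.26). Without PML palbociclib replicate 3, at the same fold changes, DNMT1, CDK4 and CDK6 passed (adjusted p = 0.000218, 0.00881 and 0.0202). CCND1, RB1, E2F1 and PML did not.

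In vector tumours the G2/M and mitosis list fell against the other genes, with a median log2 fold change of -0.47 and all 32 members negative (camera, adjusted p = 3.36e-18; adjusted p = 0.379 with an estimated correlation). Of these, 9 genes fell in the test over all genes and 23 did not pass, while 26 fell adjusted over the list alone. They included FOXM1, a transcription factor of mitotic genes (-0.86, SE 0.11, adjusted p = 0.000956), KIF20A, a mitotic kinesin (-0.87, SE 0.14, adjusted p = 0.0063), and TOP2A, a DNA topoisomerase (-0.74, SE 0.13, adjusted p = 0.00644). The list of E2F targets and DNA replication genes also fell (26 genes, median -0.34, adjusted p = 3.44e-09; adjusted p = 0.379 with an estimated correlation). GINS2 (-0.90, SE 0.11), CLSPN (-0.62, SE 0.10), MCM7 (-0.64, SE 0.14) and TYMS (-0.77) fell, 22 members did not pass, and 13 fell adjusted over the list alone. GINS2 and MCM7 encode parts of the replicative helicase, CLSPN the checkpoint adaptor claspin and TYMS thymidylate synthase.

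Among enzymes of DNA and histone methylation, EZH2 (-0.72, SE 0.14, adjusted p = 0.0124) and UHRF1 (-0.54, SE 0.10, adjusted p = 0.0094) fell and the other 17 did not pass, with 4 falling adjusted over the list alone (median -0.18, list adjusted p = 0.00542; adjusted p = 0.532 with an estimated correlation). EZH2 is a histone methyltransferase and UHRF1 recruits DNMT1. FBL, a nucleolar methyltransferase, fell by 0.50 on the log2 scale (SE 0.11) as 1 of 17 ribosome biogenesis and MYC target genes, with 2 falling adjusted over the list alone (median -0.17, list adjusted p = 0.0101; adjusted p = 0.549 with an estimated correlation). NCL (-0.32, SE 0.09) and NHP2 (-0.25, SE 0.11) did not pass. Of 17 proteins of PML nuclear bodies, the SUMO protease gene SENP1 fell (-0.58, SE 0.13), also when adjusted over the list alone, and SENP6 (-0.42, SE 0.14) and ISG20 (-0.36, SE 0.12) did not pass (median -0.16, list adjusted p = 0.0332; adjusted p = 0.622 with an estimated correlation).

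The list of senescence-associated secretory factors rose in vector tumours (20 genes, median 0.20, adjusted p = 3.53e-06; adjusted p = 0.439 with an estimated correlation). The chemokine CCL2 (1.20, SE 0.18), the growth factor binding protein IGFBP3 (1.13, SE 0.14), the collagenase MMP1 (1.09, SE 0.18) and the adhesion molecule ICAM1 (0.75, adjusted p = 0.0213) rose and 16 members did not pass, with 5 rising and 1 falling adjusted over the list alone. Lysosome and autophagy genes rose as a list (12 genes, median 0.15, adjusted p = 0.000149; adjusted p = 0.48 with an estimated correlation). Of these the cathepsin gene CTSB (0.95, SE 0.11) and the autophagy receptor SQSTM1 (0.67, SE 0.15) rose, both also adjusted over the list alone, while 10, among them LAMP2 (0.46, SE 0.17), did not pass. Interferon-stimulated genes rose (22 genes, median 0.13, adjusted p = 0.00355; adjusted p = 0.532 with an estimated correlation), with SAMD9L (0.54, SE 0.13) and IFIT2 (0.64, SE 0.16) passing, 20 such as RIGI (0.38, SE 0.12) not passing, and 3 rising adjusted over the list alone.

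In vector tumours 4 further lists passed upward. The hypoxia response list (18 genes, median 0.15, adjusted p = 0.000775; adjusted p = 0.524 with an estimated correlation) had 1 member that rose, the endoplasmic reticulum oxidase ERO1A (0.56, SE 0.10), also adjusted over the list alone, while ANGPTL4 (0.40, SE 0.13) and STC2 (0.33, SE 0.13) did not pass. None of 6 genes of MHC class I antigen presentation passed, adjusted over all genes or over the list alone (median 0.21, list adjusted p = 0.0101, or 0.524 with an estimated correlation). Values were 0.39 for TAPBP, 0.31 for ERAP1 and 0.16 for CALR. Without PML palbociclib replicate 3, at the same fold changes, TAPBP and ERAP1 passed over all genes (adjusted p = 0.00238 and 0.0265) and CALR did not. Of 14 immediate early genes CCN2 rose (0.64, SE 0.16), with DUSP1 at 0.62 and JUNB at 0.26 among the 13 that did not pass and 2 rising and 1 falling adjusted over the list alone (median 0.12, list adjusted p = 0.0332; adjusted p = 0.532 with an estimated correlation). Of 14 epithelial keratins and junction genes CLDN1 (0.89, SE 0.21) and KRT18 (0.42, SE 0.10) rose, EPCAM fell (-0.57, adjusted p = 0.0336) and 11, such as KRT19 (0.39), did not pass, with 3 rising and 1 falling adjusted over the list alone (median 0.12, list adjusted p = 0.0332; adjusted p = 0.379 with an estimated correlation). With each array centred on its median the last 2 lists were not called (adjusted p = 0.0528 and 0.0910).

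Beside these groups, endothelial markers rose as a list in vector tumours (5 genes, median 0.24, adjusted p = 0.0118; adjusted p = 0.379 with an estimated correlation), with KDR, a VEGF receptor, rising (0.78, SE 0.11, adjusted p = 0.00227), also adjusted over the list alone, and CLDN5 (0.24) and ENG (0.25) among the 4 that did not pass. FBN1, the fibrillin of microfibrils and 1 of 3 fibroblast markers tested, rose (0.67, SE 0.12, adjusted p = 0.00921). The count of 231 genes became 67, 66 and 84 without vector vehicle replicates 1, 2 and 3, 109, 88 and 53 without vector palbociclib replicates 1, 2 and 3, and 152 without PML vehicle replicate 1. Fitted on the 6 arrays of the comparison alone it was 1111.

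Under palbociclib in PML tumours 206 genes rose and 1013 fell (n = 3 per group), DNMT1, EZH2 and CDK4 among the latter. BIRC5, the mitotic regulator survivin, fell 3.31-fold (log2 fold change -1.73, SE 0.20, adjusted p = 0.000124) and TYMS 3.22-fold (-1.69, SE 0.18, adjusted p = 7.02e-05). KRTAP2-3 rose 5.45-fold (2.45, SE 0.17, adjusted p = 4.69e-06), and ANKRD1, a nuclear ankyrin repeat protein, 3.48-fold (1.80, SE 0.22, adjusted p = 0.000214). Without PML palbociclib replicate 3, 567 genes rose and 1046 fell, of which 1118 were shared with the same sign. The median over all tested genes was -0.13 here and -0.14 for PML and palbociclib together, against -0.04 and -0.03 after quantile normalization of the arrays again. Gene lists are therefore reported relative to the other genes.

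The other leading genes under palbociclib in PML tumours were KRTAP3-1 (2.41, SE 0.33), HEPHL1 (1.84, SE 0.15), SCEL, a cornified envelope precursor (1.61, SE 0.19), and OLR1, the receptor for oxidised low-density lipoprotein (1.33, SE 0.13), which rose. MAP2K6, a kinase upstream of p38 (-1.65, SE 0.26), HAS2 (-1.60, SE 0.13), MYBL2, a transcription factor of the cell cycle (-1.53, SE 0.14), and CCNA2, which encodes cyclin A2 (-1.53, SE 0.23), fell. MKI67 fell by 1.39 on the log2 scale (SE 0.13, adjusted p = 3.53e-05), DNMT1 by 0.85 (SE 0.15, adjusted p = 0.00202), E2F1 by 0.79 (SE 0.19, adjusted p = 0.0146) and CDK4 by 0.67 (SE 0.17, adjusted p = 0.0186). CDK6 (0.13, SE 0.11), CCND1 (-0.07, SE 0.13), RB1 (-0.37, SE 0.14) and PML (-0.58, SE 0.26) did not pass.

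In PML tumours 31 of the 32 G2/M and mitosis genes fell under palbociclib, all but CDCA3 (-0.44, named after its values were seen), and all 32 fell adjusted over the list alone (median -1.10, list adjusted p = 4.74e-28; adjusted p = 0.22 with an estimated correlation). FOXM1 fell by 1.49 (SE 0.11, adjusted p = 7.29e-06) and TOP2A by 1.35 (SE 0.13, adjusted p = 3.29e-05). Of 26 E2F targets and DNA replication genes 23 fell, and 24 adjusted over the list alone (median -0.79, list adjusted p = 1.30e-14; adjusted p = 0.22 with an estimated correlation). GINS2 (-1.41, SE 0.11), TYMS and CLSPN (-0.86, SE 0.10) were among them, while CCNE1 (0.26), GINS4 (-0.40) and E2F2 (-0.19), named after their values were seen, did not pass. Over the other 11 arrays, that is without PML palbociclib replicate 3, both lists were called with an estimated correlation too, at adjusted p = 0.0396 and 0.0132 and medians of -0.96 and -0.61.

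The cyclin D, CDK4/6 and RB family list fell under palbociclib in PML tumours (15 genes, median -0.38, adjusted p = 0.00376; adjusted p = 0.648 with an estimated correlation). Its 6 members that fell included E2F7, a repressor of E2F targets (-0.77, SE 0.10), TFDP1, an E2F partner (-0.67, SE 0.14), and CDK2 (-0.51, SE 0.12), 9 did not pass, and 11 fell adjusted over the list alone. Enzymes of DNA and histone methylation fell (19 genes, median -0.27, adjusted p = 0.00376; adjusted p = 0.648 with an estimated correlation), 7 members falling, among them EZH2 (-1.09, SE 0.14, adjusted p = 0.000271), DNMT1 and UHRF1 (-0.53, SE 0.10), 12 not passing and 9 falling adjusted over the list alone. Ribosome biogenesis and MYC target genes fell (17 genes, median -0.36, adjusted p = 0.00311; adjusted p = 0.648 with an estimated correlation), with FBL (-0.80, SE 0.11), TCOF1 (-0.63, SE 0.15), BOP1 (-0.60, SE 0.16) and MYC (-0.44) falling and 12 falling adjusted over the list alone. Heat shock proteins fell (9 genes, median -0.29, adjusted p = 0.0278; adjusted p = 0.682 with an estimated correlation), namely the chaperone genes BAG3 (-1.02, SE 0.20), HSPB1 (-0.87, SE 0.19) and HSPA4L (-0.47, SE 0.14), the same number adjusted over the list alone. PML nuclear body genes fell (17 genes, median -0.36, adjusted p = 0.0278; adjusted p = 0.683 with an estimated correlation), with SENP1 (-0.69, SE 0.13), SUMO2 (-0.51, SE 0.12), SUMO3 (-0.48, SE 0.12), SENP6 (-0.53) and HIPK2 (-0.48) falling and 6 falling adjusted over the list alone. The medians of these 5 lists were -0.24, -0.23, -0.22, -0.14 and -0.18 without PML palbociclib replicate 3, and the PML nuclear body list was not called (adjusted p = 0.0773). HSPA4L did not pass without that array (-0.33, adjusted p = 0.0802), while BAG3 (-0.70) and HSPB1 (-0.54) still passed.

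Interferon-stimulated genes rose under palbociclib in PML tumours (22 genes, median 0.29, adjusted p = 4.75e-06; adjusted p = 0.48 with an estimated correlation). SAMD9L (0.95, SE 0.13), SAMD9 (0.81, SE 0.16), the RNA sensors RIGI (0.68, SE 0.12) and IFIH1 (0.55), and MX2 (0.58) rose, 17 did not pass and 6 rose adjusted over the list alone. With PML palbociclib replicate 3 left out, 12 members rose with a median of 0.49, and the list was called with an estimated correlation (adjusted p = 0.0132). Immediate early genes rose as a list (14 genes, median 0.18, adjusted p = 0.0278; adjusted p = 0.648 with an estimated correlation), with DUSP1 (0.73, SE 0.17), FOSB (0.44, SE 0.13) and CCN2 (0.51, SE 0.16) rising, IER2 falling (-0.77), and the same numbers adjusted over the list alone. With each array centred on its median the list was not called (adjusted p = 0.0628). Without PML palbociclib replicate 3 FOSB did not pass (0.31, adjusted p = 0.0518), while DUSP1 and CCN2 did. The lysosome and hypoxia lists passed upward against the other genes with medians of 0.01 and -0.00, the latter opposite in sign to the test (adjusted p = 0.0278 for each; adjusted p = 0.682 for each with an estimated correlation). CTSB (0.85, SE 0.11) and SQSTM1 (0.47, SE 0.15) rose in the first, and ERO1A (0.47, SE 0.10) and STC2 (0.56, SE 0.13) in the second, also adjusted over each list alone, while UVRAG (0.18) and ADM (0.31) did not pass. The senescence-associated secretory list was not called (median -0.02 with the test upward, adjusted p = 0.0909), with CCL2 (1.06), IGFBP3 (1.05) and ICAM1 (0.70) rising and IGFBP4 (-0.84) and IGFBP5 (-0.51) falling, the same numbers adjusted over the list alone.

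Among host markers in PML tumours, FBN1 rose under palbociclib (0.56, SE 0.12, adjusted p = 0.00826), KDR did not pass (0.10, SE 0.11), and the adipocyte marker CFD fell (-0.39, SE 0.11, adjusted p = 0.0346; adjusted p = 0.162 after median centring). Smooth muscle and pericyte markers passed upward as a list (7 genes, median 0.24, adjusted p = 0.0278; adjusted p = 0.22 with an estimated correlation). MYLK (0.39, SE 0.10), a myosin kinase, rose, MCAM (-0.38) fell, DES (0.63, SE 0.21) and NOTCH3 (0.30, SE 0.12) did not pass, and 3 rose and 1 fell adjusted over the list alone. The count of 1219 genes became 573, 748 and 526 without PML vehicle replicates 1, 2 and 3 and 2269 without PML palbociclib replicate 2, and 194 in a fit on the 6 arrays alone. The split of 206 higher and 1013 lower became 553 and 897 after quantile normalization again and 605 and 936 after median centring.

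The palbociclib effects in the 2 infections ran in the same direction across genes (Pearson r 0.679 over 8862 genes, which are not independent replicates; the comparisons share no array). HAS2, GINS2, FOXM1 and TOP2A fell and HEPHL1, KRTAP2-3 and CTSB rose in both. Of the genes called in each, 175 were called in both, 68 rising and 107 falling and 0 in opposite directions, against 2.39 and 14.6 for independent lists. Without PML palbociclib replicate 3 the r was 0.713 and 876 genes were called in both. Of these 261 rose, 613 fell and 2 went in opposite directions, against 27.3 rising and 124 falling for independent lists.

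Whether palbociclib acted differently in PML and vector tumours was tested by the interaction. As a list, G2/M and mitosis genes had a more negative palbociclib effect in PML tumours, with a median interaction of -0.60 on the log2 scale and all 32 members negative (adjusted p = 8.86e-24; adjusted p = 0.306 with an estimated correlation). No gene passed in limma over all genes, the smallest adjusted p being 0.0790, while 493 genes had an unadjusted p under 0.05 against 443.1 expected, and 854 without PML palbociclib replicate 3. Adjusted over the list alone, 24 G2/M genes passed, all lower in interaction. Without PML palbociclib replicate 3, 4 genes had a positive and 2 a negative interaction, namely OLR1 (1.35), KPNA5 (0.84), GAS6-AS1 (0.76) and MYPN (0.69), and RPL23AP82 (-1.01) and BIRC5 (-0.73). KPNA5, MYPN, RPL23AP82 and BIRC5 were chosen after their values were seen. OLR1 lay below the intensity floor on every array outside the PML palbociclib group, so the size of its interaction is uncertain. A second cluster of GAS6-AS1, nearly as bright, had an interaction of 0.19 over 12 arrays against 0.72 for the cluster kept.

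Among G2/M genes the interaction was -0.97 (SE 0.25) for CDK1, the mitotic kinase, -0.63 (SE 0.16) for FOXM1, -0.62 (SE 0.16) for KIF2C and -0.69 (SE 0.19) for MKI67, none passing over all genes (adjusted p = 0.701 for each). E2F targets and DNA replication genes had a median interaction of -0.39, all 26 negative (adjusted p = 5.86e-10; adjusted p = 0.44 with an estimated correlation), with 7 passing adjusted over the list alone. Their values included -0.91 (SE 0.25) for TYMS, -0.60 (SE 0.16) for RRM2, a subunit of ribonucleotide reductase, and -0.59 (SE 0.16) for GINS3. The G2/M and E2F medians were -0.42 and -0.24 without PML palbociclib replicate 3, and both lists were then called with an estimated correlation (adjusted p = 0.0457 and 0.0297). The mean log2 intensity of the 32 G2/M genes was 7.74 to 7.78 in vector vehicle, 7.17 to 7.33 in vector palbociclib, 7.50 to 7.60 in PML vehicle and 6.15 to 6.70 in PML palbociclib tumours.

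**Figure D2:**
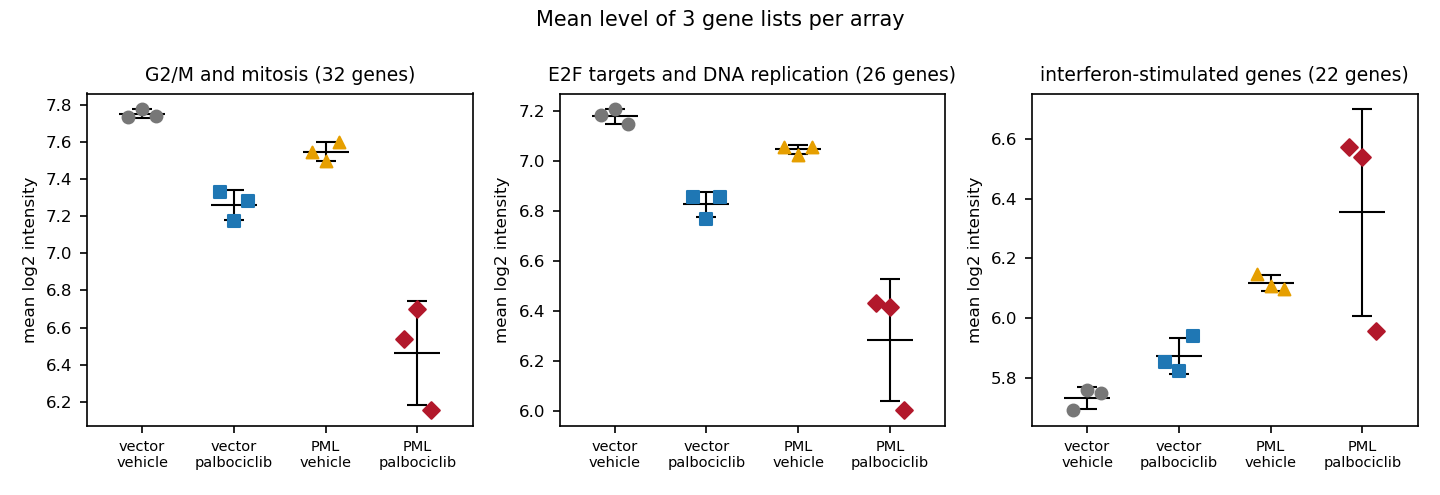
Mean log2 intensity (y axis) of the tested G2/M and mitosis genes (32), E2F targets and DNA replication genes (26) and interferon-stimulated genes (22) in the 4 groups, with 1 point per array and bars for the group mean and SD (n = 3). The 3 PML palbociclib arrays lie between 6.15 and 6.70 for the G2/M list, below all other arrays, and PML palbociclib replicate 3 has the lowest value there and, at 5.96, the lowest interferon value of its group.

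Interferon-stimulated genes had a positive interaction (22 genes, median 0.08, adjusted p = 0.00308; adjusted p = 0.847 with an estimated correlation), with 0.57 (SE 0.23) for SAMD9, 0.41 (SE 0.18) for SAMD9L and 0.48 (SE 0.25) for IFIH1 and 0 genes passing adjusted over the list alone. The median was 0.25 without PML palbociclib replicate 3 and the list was then called with an estimated correlation (adjusted p = 0.0297), but without PML palbociclib replicate 1 the list was not called (adjusted p = 0.0845). The cyclin D, CDK4/6 and RB family list had a negative interaction (median -0.23, adjusted p = 0.0232; adjusted p = 0.847 with an estimated correlation), with -0.38 for E2F7, -0.36 for RBL2 and -0.43 for E2F3. Senescence-associated secretory factors likewise (median -0.19, adjusted p = 0.0188; adjusted p = 0.847 with an estimated correlation) had -0.59 (SE 0.16) for IGFBP5, which alone passed adjusted over the list alone, -0.47 for MMP14 and -0.69 for MMP1. Smooth muscle and pericyte markers had a test upward with a median of -0.01 and a mean of 0.15 (adjusted p = 0.0228; adjusted p = 0.306 with an estimated correlation), with 0.34 for MYLK, 0.35 for NOTCH3 and 0.65 for DES. The last 3 lists were not called without PML palbociclib replicate 3 (adjusted p = 0.0710, 0.0651 and 0.142).

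The genes with the smallest interaction p, none passing, were OLR1 (1.24, SE 0.19, adjusted p = 0.0790), GAS6-AS1 (0.72, SE 0.14) and CEP290, a centrosomal protein (0.58, SE 0.14), and, on the negative side, HEPHL1 (-1.15, SE 0.22), SPDEF, an epithelial ETS factor (-0.76, SE 0.17), and KDR (-0.69, SE 0.16). OLR1 had log2 intensities of 3.40 ± 0.05 (SD, n = 3) in vector vehicle and 5.51 ± 0.19 in PML palbociclib tumours. Its means in vector vehicle (3.40), vector palbociclib (3.49) and PML vehicle tumours (4.18) lay below the intensity floor. Only the PML palbociclib arrays reached the floor, so the size of the OLR1 interaction is uncertain. CCND1 (-0.26, SE 0.19), DNMT1 (-0.28, SE 0.21), CDK4 (-0.23, SE 0.24), CDK6 (-0.16, SE 0.15), RB1 (-0.22, SE 0.19), E2F1 (-0.60, SE 0.27) and PML (-0.84, SE 0.37) did not pass either. With each array centred on its median OLR1 passed, the 1 gene to do so.

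**Figure D3:**
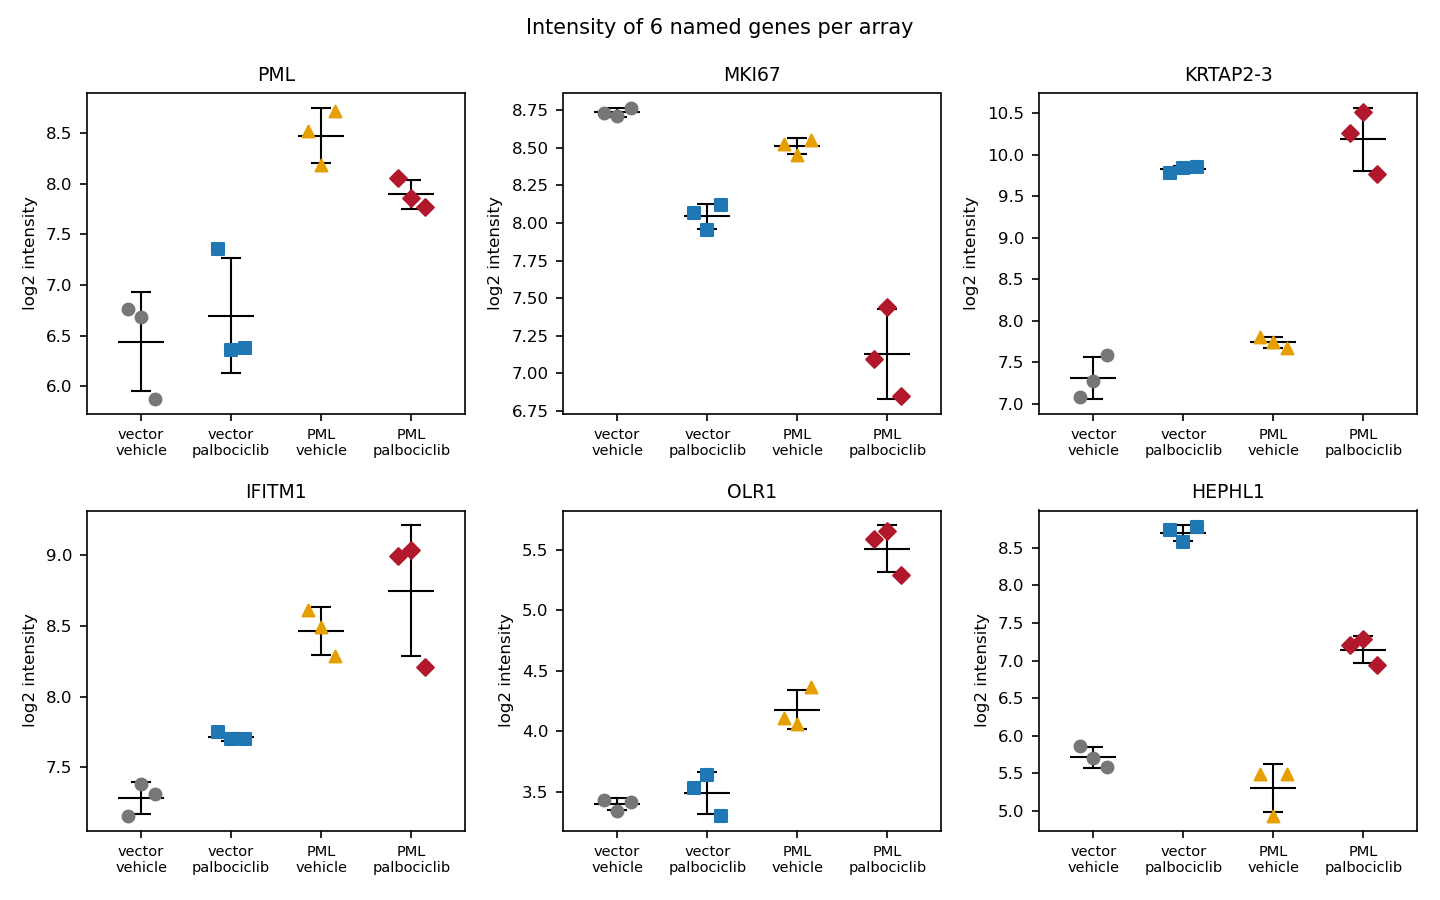
Log2 intensity (y axis) of PML, MKI67, KRTAP2-3, IFITM1, OLR1 and HEPHL1 in the 4 groups, with 1 point per array and bars for the group mean and SD (n = 3). MKI67 has its lowest values in the PML palbociclib tumours, KRTAP2-3 and HEPHL1 are higher in all palbociclib than in all vehicle tumours, and OLR1 is highest in the PML palbociclib tumours.

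PML under vehicle changed few genes one by one. Besides PML, 7 genes rose and 0 fell (n = 3 per group; 373 genes at an unadjusted p under 0.05 in limma against 443.1 expected, and 1135 without PML palbociclib replicate 3). CPA4 rose 2.33-fold (log2 fold change 1.22, SE 0.13, adjusted p = 0.00147) and SLPI, a secreted protease inhibitor, 2.27-fold (1.18, SE 0.14, adjusted p = 0.00179). IFITM1, an interferon-induced membrane protein, rose 2.27-fold (1.18, SE 0.18, adjusted p = 0.0241). ADGRF4, an adhesion receptor (0.99, SE 0.16), and AGR2, a disulfide isomerase of secretory cells (0.87, SE 0.14), rose too, as did CLU (0.75, SE 0.12) and OLR1 (0.78, SE 0.13), which were named after their values were seen. Both group means of ADGRF4 (3.87 and 4.87) and of OLR1 (3.40 and 4.18), and the vector mean of AGR2 (4.64), lay below the floor of 5, so the sizes of these 3 changes are uncertain. Without PML palbociclib replicate 3, 70 genes rose and 30 fell, all 8 genes among them. That array enters this comparison only through the spread, so the fold changes are the same by construction. MKI67 (-0.22, SE 0.13), DNMT1 (-0.12, SE 0.15), CDK4 (-0.05, SE 0.17), CDK6 (0.18, SE 0.11), CCND1 (-0.20, SE 0.13), RB1 (-0.13, SE 0.14) and E2F1 (-0.01, SE 0.19) did not pass.

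Interferon-stimulated genes rose as a list with PML under vehicle (22 genes, median 0.34, 20 positive, adjusted p = 1.05e-18; adjusted p = 0.23 with an estimated correlation). IFITM1 alone passed over all genes, and 5 members rose adjusted over the list alone, with values of 0.81 (SE 0.16) for SAMD9 and 0.65 (SE 0.12) for IRF9, a transcription factor of the interferon response. The list was called with an estimated correlation without PML palbociclib replicate 3 (adjusted p = 0.00242). G2/M and mitosis genes fell as a list (median -0.21, 31 of 32 negative, adjusted p = 5.05e-11; adjusted p = 0.699 with an estimated correlation), with no member passing over all genes or adjusted over the list alone and -0.29 for CDCA8, -0.24 for KIF2C and -0.27 for TOP2A. E2F targets and DNA replication genes did likewise (median -0.15, adjusted p = 0.000182; adjusted p = 0.699 with an estimated correlation), with -0.32 for CLSPN, -0.22 for MCM4 and -0.24 for GINS2.

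No member passed, over all genes or adjusted over the list alone, in the other lists called with PML under vehicle. The hypoxia response (median -0.13, adjusted p = 0.0057), DNA and histone methylation enzymes (median -0.12, adjusted p = 0.00791) and ribosome biogenesis and MYC targets (median -0.07, adjusted p = 0.0416) were lower, and p53 targets higher (13 genes, median 0.17, adjusted p = 0.0416). For each, adjusted p = 0.699 with an estimated correlation. Values were -0.24 for VEGFA, -0.24 for HK2, -0.23 for ANGPTL4, -0.22 for TET2, -0.13 for EHMT2, -0.17 for CBX5, -0.17 for ODC1, -0.17 for NCL and -0.14 for FBL. SUSD6 stood at 0.27, PLK2 at 0.22 and TIGAR at 0.19. Among host markers FBN1 (-0.34, SE 0.12) and KDR (-0.09, SE 0.11) did not pass. The count of 8 genes became 4, 3 and 3 without vector vehicle replicates 1, 2 and 3, 3, 3 and 2 without PML vehicle replicates 1, 2 and 3, and 3 without vector palbociclib replicate 2. It was 78 in a fit on the 6 arrays alone, 19 higher and 5 lower after quantile normalization again, and 21 and 5 after median centring.

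With PML under palbociclib 106 genes rose and 365 fell (n = 3 per group). OLR1 rose (log2 fold change 2.02, SE 0.13, adjusted p = 2.25e-06), from a vector palbociclib mean of 3.49 below the floor of 5, so the size of its change is uncertain. ANKRD1 rose 3.56-fold (1.83, SE 0.22, adjusted p = 0.00107) and SAMD9 2.61-fold (1.38, SE 0.16, adjusted p = 0.00107). HEPHL1 fell 2.94-fold (-1.55, SE 0.15, adjusted p = 0.000201) and BIRC5 2.41-fold (-1.27, SE 0.20, adjusted p = 0.00264). Without PML palbociclib replicate 3, 476 genes rose and 481 fell, of which 458 were shared with the same sign. ADGRF4 (1.26, SE 0.16) and SCEL (1.23, SE 0.19) rose, and IGFBP5 (-1.20, SE 0.11), LXN, the carboxypeptidase inhibitor latexin (-1.18, SE 0.16), and CDK1 (-1.17, SE 0.18) fell. MKI67 fell by 0.92 on the log2 scale (SE 0.13, adjusted p = 0.00202), while CCND1 (-0.46, SE 0.13, adjusted p = 0.0567), E2F1 (-0.60, SE 0.19), DNMT1 (-0.40, SE 0.15), RB1 (-0.35, SE 0.14), CDK4 (-0.28, SE 0.17) and CDK6 (0.03, SE 0.11) did not pass.

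Of 32 G2/M and mitosis genes 31 were lower with PML under palbociclib, over all genes and adjusted over the list alone, with CDCA3 (-0.25) as the exception over all genes (median -0.80, list adjusted p = 1.66e-27; adjusted p = 0.148 with an estimated correlation). KIF2C (-0.86, SE 0.11), FOXM1 (-0.81, SE 0.11) and TOP2A (-0.87, SE 0.13) fell. Of 26 E2F targets and DNA replication genes 15 fell, and 24 adjusted over the list alone (median -0.54, list adjusted p = 4.47e-13; adjusted p = 0.201 with an estimated correlation), among them RRM2 (-0.79, SE 0.11), GINS2 (-0.76, SE 0.11) and TYMS (-1.06, SE 0.18). The medians were -0.61 and -0.42 without PML palbociclib replicate 3, and both lists were then called with an estimated correlation (adjusted p = 0.0383 and 0.0152). Interferon-stimulated genes rose (22 genes, median 0.46, adjusted p = 1.13e-14; adjusted p = 0.148 with an estimated correlation), 9 members rising, among them SAMD9, SAMD9L (1.02, SE 0.13) and IRF9 (0.72, SE 0.12), 13 not passing, and 12 rising adjusted over the list alone. With PML palbociclib replicate 3 left out, 16 rose with a median of 0.63, and the list was called with an estimated correlation (adjusted p = 0.00267).

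The cyclin D, CDK4/6 and RB family list fell with PML under palbociclib (15 genes, median -0.35, adjusted p = 0.00225; adjusted p = 0.781 with an estimated correlation), with E2F7 falling (-0.63, SE 0.10), CCND1 and CDK2 (-0.40, SE 0.12) not passing, and 8 falling adjusted over the list alone. The methylation list fell (19 genes, median -0.29, adjusted p = 0.00948, or 0.809 with an estimated correlation). Its 1 member that fell was CBX3, a heterochromatin protein and not a methylation enzyme (-0.56, SE 0.13). CBX5 (-0.46) and the demethylase KDM1A (-0.45) did not pass, and 7 fell adjusted over the list alone. Ribosome biogenesis and MYC targets fell (17 genes, median -0.23, adjusted p = 0.00948; adjusted p = 0.809 with an estimated correlation), with FBL (-0.44, SE 0.11) and TCOF1 (-0.56, SE 0.15) falling, ODC1 (-0.29) not passing, and 3 falling adjusted over the list alone. Smooth muscle and pericyte markers passed upward (7 genes, median 0.01, adjusted p = 0.00948; adjusted p = 0.148 with an estimated correlation), with MYLK rising (0.65, SE 0.10), DES (0.70) and MCAM (0.13) not passing, and 2 rising adjusted over the list alone. The smooth muscle list was not called without PML palbociclib replicate 3 (adjusted p = 0.0600). KDR (-0.77, SE 0.11, adjusted p = 0.00204) and FBN1 (-0.45, SE 0.12, adjusted p = 0.0433), both among the host markers, fell. With the host marker covariate FBN1 did not pass (-0.44, adjusted p = 0.13). The count of 471 genes became 155, 217 and 190 without vector palbociclib replicates 1, 2 and 3 and 1114 without PML palbociclib replicate 2, and 4 in a fit on the 6 arrays alone. The split of 106 higher and 365 lower became 356 and 460 after quantile normalization again and 325 and 581 after median centring.

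Across genes, the PML effect under vehicle and that under palbociclib had a Pearson r of 0.481. All 8 genes called under vehicle, PML and IFITM1 among them, were called with the same sign under palbociclib, against 0.0957 expected for independent lists. Without PML palbociclib replicate 3 the r was 0.549 and 84 of 100 genes called under vehicle were called under both. Of these 61 rose and 23 fell, against 3.76 and 1.63.

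With PML and palbociclib together, set against vector and vehicle, all 32 G2/M genes fell (median -1.31, list adjusted p = 1.97e-26; adjusted p = 0.193 with an estimated correlation), and 12 of 22 interferon-stimulated genes rose (median 0.64, list adjusted p = 1.11e-12; adjusted p = 0.193 with an estimated correlation). Adjusted over the list alone, 32 fell and 14 rose. Altogether 411 genes rose and 1682 fell, or 943 and 1606 without PML palbociclib replicate 3 (1876 shared). KRTAP3-1 (3.21, SE 0.33), KRTAP2-3 (2.88, SE 0.17), ANKRD1 (2.86, SE 0.22), CPA4 (2.51, SE 0.13), SCEL (2.14, SE 0.19) and OLR1 (2.11, SE 0.13) rose. HAS2 (-2.03, SE 0.13), MAP2K6 (-1.98, SE 0.26), BIRC5 (-1.95, SE 0.20), TYMS (-1.83, SE 0.18) and CCNA2 (-1.82, SE 0.23) fell. Among host markers DES (0.68, SE 0.21) and CIDEA (0.58, SE 0.13) rose and CFD (-0.37, SE 0.11) fell. DES did not pass without PML palbociclib replicate 3 (adjusted p = 0.101), nor CFD after quantile normalization again or median centring (adjusted p = 0.0567 and 0.173). The count of 2093 became 1223 and 1149 without vector vehicle replicates 1 and 2, and 727 in a fit on the 6 arrays alone. The split became 962 and 1336 after quantile normalization again and 993 and 1446 after median centring.

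Averaged over infections, palbociclib raised 343 genes and lowered 1375 (6 against 6 arrays), led by KRTAP3-1 (2.73, SE 0.23), KRTAP2-3 (2.48, SE 0.12), HEPHL1 (2.42, SE 0.11), ESM1 (2.84-fold), CPA4 (1.49, SE 0.09) and ANKRD1 (1.41, SE 0.16). HAS2 (-1.41, SE 0.09), MAP2K6 (-1.28, SE 0.18), TYMS (-1.23, SE 0.12), SULF2 (-1.22, SE 0.11), BIRC5 (-1.20, SE 0.14) and MBOAT1 (-1.20, SE 0.13) fell. Among host markers FBN1 (0.62, SE 0.09), KDR (0.44, SE 0.08) and CIDEA (0.29, SE 0.09) rose and CFD (-0.32, SE 0.08; adjusted p = 0.0764 after median centring) fell. The numbers were 911 and 1809 without PML palbociclib replicate 3 (1711 shared), and the total of 1718 became 1140 without vector vehicle replicate 2, 1124 without PML vehicle replicate 3 and 2584 without PML palbociclib replicate 2. The split became 813 and 1193 after quantile normalization again and 944 and 1231 after median centring.

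Averaged over agents, PML raised 128 genes and lowered 298 (6 against 6 arrays). PML (1.61, SE 0.19), ANKRD1 (1.45, SE 0.16), OLR1 (1.40, SE 0.09), SLPI (1.16, SE 0.10), ADGRF4 (1.13, SE 0.11) and IFITM1 (1.11, SE 0.13) rose. HEPHL1 (-0.98, SE 0.11), IGFBP5 (-0.90, SE 0.08), CD24 (-0.88, SE 0.12), LXN (-0.87, SE 0.12) and the noncoding LINC00261 (-0.76, SE 0.13) fell. The host markers FBN1 (-0.40, SE 0.09) and KDR (-0.43, SE 0.08) fell too. The numbers were 543 and 604 without PML palbociclib replicate 3 (426 shared). The total of 426 became 224, 185 and 208 without vector vehicle replicates 1, 2 and 3, 183, 263 and 239 without vector palbociclib replicates 1, 2 and 3, 195, 192 and 234 without PML vehicle replicates 1, 2 and 3, and 735 without PML palbociclib replicate 2, and the split became 346 and 382 after quantile normalization again.

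The remaining lists were called in none of the comparisons by camera with the preset correlation. By fry, androgen receptor targets were lower with PML under palbociclib (adjusted p = 0.00728), with PML averaged over agents (0.0126) and with both together (0.0285). Oxidative phosphorylation genes were lower by fry with both together (adjusted p = 0.0409). Under palbociclib in vector tumours 1 of 16 cholesterol synthesis genes, HMGCS1, rose (0.82; list median -0.01 with the test upward, adjusted p = 0.175), 1 of 13 genes of the unfolded protein and amino acid stress response, PHGDH, fell (-0.56; list median -0.10, adjusted p = 0.302), and 1 of 5 androgen receptor targets, HPGD, rose (0.51; list median 0.04, adjusted p = 0.213). None of 8 oxidative phosphorylation genes (median -0.09, adjusted p = 0.434) or 11 mesenchymal genes (median -0.10, adjusted p = 0.690) passed. Adjusted over the list alone, the numbers for these 5 lists were 1, 1, 1, 0 and, for the mesenchymal genes, 1 higher and 1 lower. HMGCS1, PHGDH and HPGD were named after their values were seen. Host lists with under 5 tested genes were not tested, and their brightest members had values under palbociclib in vector tumours of -0.12 for PCOLCE (fibroblasts), -0.10 for CD68 and 0.05 for SPI1 (myeloid cells), 0.06 for CCL5 and 0.28 for NKG7 (lymphoid cells), 0.10 for TCAP and 0.54 for TNNC2 (skeletal muscle), -0.25 for CFD and 0.21 for CIDEA (adipocytes), 0.12 for SBSN and -0.02 for KRTDAP (keratinocytes), and 0.28 for KLF1 and 0.07 for EPB42 (erythroid cells). None of these 13 passed. Cyclin D, CDK4/6 and RB family genes (15 genes, median -0.15, adjusted p = 0.0696, E2F7 falling by 0.40), heat shock proteins (9 genes, median -0.12, adjusted p = 0.0606) and p53 targets (13 genes, median 0.04, adjusted p = 0.193) were not called in that comparison. Smooth muscle and pericyte markers were not called there (7 genes, median 0.02, adjusted p = 0.627), with -0.02 for DES and 0.02 for CSPG4.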

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

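The wrong label and the G2/M interaction without PML palbociclib replicate 3 were tests chosen only after their result had been seen, and the way of splitting the samples for the interaction was changed after the first splits were seen. The predictions of the other tests were written before they were computed, but after the outlying array and the interaction had been seen. The results below were flagged because a test of the difference between PML and vector tumours passed, or because transcript clusters that the report does not use changed.

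PML palbociclib replicate 3 stood apart from the other 11 arrays (SD 1.88 against 2.05 to 2.11). Its difference from its group mates had a squared correlation of 0.129 with the mean level of a tested gene, so a straight line with level left most of it. The median difference was -0.08, -0.37 and -0.49 from the dimmest to the brightest tested genes. It was 0.09 for clusters without a symbol, whose median on this array was 4.03. The test left out genes below the floor, so it cannot exclude a compressed scale. Its PML value of 7.77 lay above the highest vector array (7.35), and its KRTAP2-3 value of 9.77 above the highest vehicle array (7.80), which a wrong label would not give. The squared correlation with the palbociclib effect of vector tumours was 0.0194 (r 0.139), so a stronger response along that effect left most of it. The cell cycle lists differed by a median of -0.48, against -0.35 over all tested genes and -0.49 for the brightest. A stronger response of a kind particular to PML tumours was not tested and stays possible. RNA quality might differ, but it was not tested, and no other biological explanation was tested.

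The interaction was flagged for G2/M and mitosis genes (median -0.60, 32 of 32 negative, adjusted p = 8.86e-24) and for E2F targets (median -0.39, 26 of 26 negative, adjusted p = 5.86e-10). Without PML palbociclib replicate 3 the G2/M median was -0.42, and with the host marker covariate -0.52. Neither that array alone nor a trend with the mean of the 12 markers therefore accounts for the interaction. That mean was lowest on the same array (-0.163) and was not shown to measure host RNA, so host RNA is not excluded. Among genes that rose under palbociclib, the median ratio of interaction to average effect was 0.189 over 11 arrays, and it was 0.145 for genes that fell outside the 2 lists, 0.611 for G2/M genes and 0.499 for E2F targets. A generally stronger response in PML tumours could therefore account for part of it, and the test cannot tell. With an estimated correlation the calls were lost over 12 arrays (adjusted p = 0.306 and 0.44) and made over 11 (adjusted p = 0.0457 and 0.0297). By fry over 12 arrays they were lost too (adjusted p = 0.122 and 0.19). A larger effect of palbociclib on the cell cycle with PML stays a hypothesis.

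Another 4 lists were flagged by the interaction test: interferon-stimulated genes (median 0.08, 15 of 22 positive, adjusted p = 0.00308), senescence-associated secretory factors (median -0.19, 18 of 20 negative, adjusted p = 0.0188), smooth muscle and pericyte markers (median -0.01, 3 of 7 positive, adjusted p = 0.0228) and the cyclin D, CDK4/6 and RB family (median -0.23, 15 of 15 negative, adjusted p = 0.0232). With an estimated correlation none of these 4 was called (adjusted p = 0.847, 0.847, 0.306 and 0.847), and without PML palbociclib replicate 3 the interferon list was called with it (adjusted p = 0.0297), while the last 3 were not called with the preset correlation either (adjusted p = 0.0651, 0.142 and 0.0710). Of 11955 tested clusters without a symbol, 273 were higher on average under palbociclib and 46 with PML.

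Counts were set against other splits of the samples. The averaged palbociclib effect had 1718 genes and the highest other of 100 splits 34, and the averaged PML effect 426 and 27, so the real split was the 1 with the most genes in both. For the interaction the real count was 0, which all 100 splits reach whatever the data (highest other 0), so this test shows nothing. For the other comparisons 10 splits are too few: the real counts were 231 (palbociclib in vector tumours), 1219 (palbociclib in PML tumours), 8 (PML under vehicle), 471 (PML under palbociclib) and 2093 (both together), each 1 of 10, with a highest other of 0.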

How the results depend on the processing

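Only the settings without PML palbociclib replicate 3 beside each count, the estimated correlation without it and the gene-by-gene array weights were chosen after the results had been seen. Counts are given in the order palbociclib in vector tumours (231), palbociclib in PML tumours (1219), PML under vehicle (8), PML under palbociclib (471), interaction (0), both together (2093), palbociclib averaged (1718) and PML averaged (426), and only those moved by over 1.5 times are named; the correlation of the palbociclib effects was 0.679. Among the genes the rule names, and among the lists, no called result changed direction under the settings run for it, while 195 gene results and 88 list results that were not called did. Lists were run with no filter, median centring, the replicate block, the host covariate, fry, the estimated correlation and each array left out, and not with the other settings. The floor of 6, the mean of clusters, every cluster on its own and eBayes with trend and robust left each count within 1.5 times.

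With no intensity filter the counts were 112 (palbociclib in vector tumours), 3 (PML under vehicle), 293 (PML under palbociclib) and 253 (PML averaged), and the correlation 0.558; more and dimmer genes were tested there. With a floor of 6 the correlation was 0.738. Quantile normalization again gave 492, 24, 816 and 728 for the same 4 counts, and median centring 579, 26, 906 and 887, with 1 for the interaction. A fit on the groups of a comparison alone, with fewer arrays behind the spread, gave 1111, 194, 78, 4 and 727 (both together). The 1111 and 78 came from comparisons without the PML palbociclib group and were higher than in the main fit. The 194, 4 and 727 came from comparisons with that group and were lower. Fewer arrays alone do not account for both directions. The shared spread of the main fit may be too wide for the former comparisons and too narrow for the latter. Array weights gave 1646, 270 and 873 for palbociclib in vector tumours, PML under vehicle and PML under palbociclib, 11 for the interaction, and 2927 and 1339 for the averages. The weight of PML palbociclib replicate 3 was 0.047, against 0.76 to 2.42 on the other arrays. The host marker covariate gave 2202 for palbociclib in PML tumours, 20 and 199 for PML under vehicle and palbociclib, 1 for the interaction and 2846 for palbociclib averaged, with a correlation of 0.794. A fold of at least 2 as well gave 20, 110, 4, 44, 203 (both together), 36 and 9, fewer by construction, and an adjusted p under 0.1 gave 365, 1951, 13, 823, 1 and 648 (PML averaged), more by construction. For the others the cause was not tested.

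Leaving out each array in turn gave 53 to 1478, 526 to 2269, 2 to 100, 155 to 1114, 0 to 6, 1149 to 2977, 1124 to 2720 and 183 to 1147 for the 8 counts, and 0.618 to 0.713 for the correlation. With the replicate block the counts were 164, 1082, 9, 377, 0, 1931, 1583 and 333 and the correlation 0.679. Same-numbered arrays did not deviate together: the 18 pairs had a median r of 0.00019 and 3 over 0.1, and 3 of 12 arrays correlated best with their own number. With the estimated correlation all 76 list calls were lost over 12 arrays, and 23 held over 11. By fry over 12 arrays 41 of the 76 were lost. Another 4 list results not called before were called, all of androgen receptor targets or oxidative phosphorylation. The lists called for the interaction and for PML under vehicle were all among those lost. The number of arrays limits every fold change, and signal over background limits the dim genes.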

Other observations

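The overlap of the averaged effects and the named examples were chosen only after the results had been seen, and the prediction for the last test below was written before it was computed. Averaged over the other factor, palbociclib and PML both raised 53 genes and both lowered 194, against 4.95 and 46.2 for independent lists. ANKRD1 (1.41 with palbociclib, 1.45 with PML), CPA4 (1.49, 1.02), CCL2 (1.13, 0.95), SCEL (1.26, 0.88), ADGRF4 (0.80, 1.13) and SLPI (0.76, 1.16) rose in both. BIRC5 (-1.20, -0.74), CCNA2 (-1.10, -0.72), MAP2K6 (-1.28, -0.70), CDK1 (-0.95, -0.69) and KIF14 (-1.05, -0.69) fell in both. For BIRC5 the vector and PML means were 8.54 and 8.33 under vehicle, but 7.87 and 6.60 under palbociclib. For CCNA2 they were 8.41 and 8.12, then 7.73 and 6.58. With PML under vehicle 0 genes were called lower. A low value in the PML palbociclib group alone enters both averages with the same sign, so the overlap does not show separate effects. Palbociclib raised and PML lowered 23 genes (11.5 for independent lists), among them HEPHL1 (2.42, -0.98), CD24 (1.13, -0.88), MMP1 (0.74, -0.73), IL37 (0.96, -0.70) and NPY1R (0.70, -0.63). Palbociclib lowered and PML raised 3 (19.9), namely STOX1 (-0.39, 0.55), ENPP1 (-0.53, 0.37) and ACTMAP (-0.42, 0.42). Across genes r was 0.501, where the design gives a noise correlation of 0, but PML palbociclib replicate 3 enters both with the same sign. Without it the 4 numbers were 220, 372, 53 and 29 (55.8, 123, 62.1 and 111 for independent lists) and r was 0.414, with a noise correlation of 0.111.

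Among 11955 clusters without a symbol, palbociclib raised 273 and lowered 870 on average (745 and 1337 without PML palbociclib replicate 3), led by 16852871 (2.07) and 17049676 (1.76) upward and 17005865 (-1.87) and 16669437 (-1.50) downward. PML raised 46 and lowered 65 (224 and 359), led by 16962316 (2.08) and 16907324 (0.90) upward and 16978046 (-0.76) and 16728287 (-0.58) downward.

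PML under vehicle and palbociclib in vector tumours share the vector vehicle arrays. Their covariance across genes was 0.0126, against a mean of 0.00629 and a highest value of 0.0301 over 100 simulations of unchanged groups. The r was 0.366 against a simulated mean of 0.510. The simulated groups held no palbociclib effect, which widens the spread of the real fold changes, so these r values are not comparable. The covariance lay within the simulated range. The simulations drew whole-array residuals with replacement, so 1 array's residual could enter both compared groups and widen that range. With independent genes the simulated mean covariance was 0.00607. The test therefore cannot tell whether shared controls alone gave the covariance. It gave evidence neither for nor against PML moving genes along the palbociclib effect.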
